A study of Mus musculus with 28 samples.

How the data were processed

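RNA was measured in 28 libraries of hippocampal CA1 from mice 3 to 4 weeks old that carry an HA-tagged Rpl22 gene switched on by CaMK2a-Cre or PV-Cre. Per the labels tissue was taken 6 h after kainic acid or PBS, and each lysate pool gave an input library and an anti-HA IP library. The deposited column names give the PBS groups an earlier time than the kainic acid groups. Per the labels, pools held 4 mice in the CaMK2a line and 9 to 10 in the PV line, library preparation began from 20 ng and 2.5 ng of RNA, the IP used 12 µg of antibody, fragments were about 400 bp and reads 75 bp, and 20 to 40 M reads were sequenced per library. The totals per library behind the deposited RPKM columns run from 20.1 to 54.4 M, so some lie above that stated range. Strandedness is not stated, so reads of genes that overlap on opposite strands cannot be told apart.

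The authors aligned reads to mm10 (GRCm38) with BWA and compared groups with edgeR, versions not stated. The deposited tables hold coding genes with a sum of at least 4 reads. Genes higher and genes lower in a comparison were deposited apart and were joined here into 1 table per comparison. The deposited counts are whole numbers of reads per gene and library, and they were the values analysed here. The deposited RPKM columns are reads scaled to the listed length and to a library total larger than the sum of the gene counts. The deposited CPM column was not used. The deposited fold change is a linear ratio of the first group to the second. The deposited p-value and FDR columns come from the authors' edgeR analysis, whose test is not stated. The 6 tables hold 13384 to 14033 genes. Counts of a library that 2 tables share were compared, and none of 79845 in the CaMK2a line or 109436 in the PV line differed. Of 14711 genes in any table, 14464 gene IDs are in the RefSeq annotation of GRCm38.p6, and 14460 overlap its coordinates.

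Groups follow the labels: Cre line, kainic acid or PBS, and IP or input, with 3 libraries per group in the CaMK2a line and 4 in the PV line. Kainic acid was compared with PBS in each of 4 fractions, IP with input in each line after each treatment, and 3 differences of kainic acid effects were tested in a model of group means: IP minus input in each line, and CaMK2a IP minus PV IP. The deposited comparisons include no table of IP against input after PBS, which was built here from the counts of the other tables. Tests were edgeR 4.0.16 quasi-likelihood tests with TMM factors, filterByExpr with a minimum count of 10, a prior count of 0.125 and a Benjamini-Hochberg adjusted p threshold of 0.05, in R 4.3.3. SE was taken as the size of the log2 fold change over the square root of F. CPM values are given with TMM factors of the libraries compared, and CPM of single PV libraries in the closing part with TMM factors over all 16 PV libraries and all genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 read the tables and drew the figures.

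The comparisons, the tests, 20 response lists, 14 lists of cell type markers, the rule for naming genes and the alternatives were set before the data were examined, apart from 2 alternatives on PV replicate 4. Lists were tested with limma 3.58.1 camera on voom values with a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated from the data. That estimate rests on 3 or 4 libraries per group, and lists were simulated with the preset correlation only. How often a changed list passes with the estimate is therefore unknown, and a call that ended with it is not shown to be absent. Members were counted by direction over all genes and adjusted over the list alone. Genes were named by rule: among those with adjusted p under 0.05, mean log2 CPM of at least 3, no overlap between the values of the groups and a symbol that is not a clone or predicted gene, the 8 largest rises and 8 largest falls, or 5 and 5 for differences of effects, where no overlap rule applied. Fos, Fosb, Npas4, Scg2, Bdnf, Inhba, Rgs2, Nptx2 and Pcsk1 were fixed in advance for kainic acid, and Camk2a, Slc17a7, Pvalb, Gad1, Slc32a1, Sst, Gfap, Mbp, Cx3cr1, Cldn5 and Rpl22 for IP against input, besides up to 4 members of each list with the largest changes. Of 109 genes named by rank or fixed in advance 104 were found in GENCODE M21, and 13 of them, Bdnf and Slc32a1 among these, share exonic bases with a gene on the opposite strand. So do 69 of 349 further list members with the largest changes, Gabra5, Cyp51 and Mt2 among them.

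Alternatives were relative log expression and upper-quartile factors, no filter and a stricter filter on low counts (at least 10 counts in every library of a group), DESeq2 1.42.0 Wald tests, replicate number as a block, a fit to all groups of a line, and each library left out in turn. PV replicates 1 to 3 only and a term for PV replicate 4 were added after seeing the data. Depth was 6.06 to 15.8 M counts per library. Simulated changes in these libraries, at 2-fold and 4-fold, were recovered at 58.2% and 92.4% in the CaMK2a IP, 79.1% and 90.9% in the CaMK2a input, 31.3% and 77.3% in the PV IP, and 43.3% and 90.9% in the PV input. Each simulation changed 67 genes 1.5-fold, 67 genes 2-fold and 66 genes 4-fold. Outside the differences of effects these are fewer genes than were called in the data. Without the block no library effect was added, so recovery in the data can differ. In differences of effects recovery was 50.7% and 86.4% for the CaMK2a line, 8.96% and 39.4% for the PV line and 4.48% and 47.0% between the IPs. Of the simulated calls 3.12% to 13.5% were false without a block over the 11 comparisons, and up to 10.9% with it. The RPKM, CPM and p-value columns were not used for the tests, and noncoding genes were not analysed here since the tables hold none.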

Results

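Hippocampal CA1 was taken from mice in which Cre recombinase, driven by the CaMK2a gene or by the parvalbumin (PV) gene, tags the ribosomal protein Rpl22 with an HA epitope. Ribosomes with their transcripts can then be pulled with an anti-HA antibody (IP). The mice received PBS or kainic acid, a glutamate receptor agonist that provokes seizures, and per the labels tissue was collected 6 h later. The deposited column names give the PBS groups an earlier time, so the time after PBS is uncertain. RNA of the IP and of the lysate before the IP (input) was sequenced in 8 groups, with 3 libraries per group in the CaMK2a line and 4 libraries per group in the PV line. A CaMK2a library came from 4 pooled mice and 20 ng of RNA, and a PV library from 9 to 10 pooled mice and 2.5 ng of RNA. The 28 libraries held 6.06 to 15.8 M counted reads in coding genes. Group means ± SD in M were 9.04 ± 0.975 and 11 ± 3.95 for the CaMK2a IP after kainic acid and PBS, and 7.62 ± 1.39 and 9.15 ± 2.04 for the matching inputs. They were 12.6 ± 2.22 and 12.6 ± 0.616 for the PV IP after kainic acid and PBS, and 9.31 ± 0.906 and 9.65 ± 1.04 for the matching inputs. The share of counts in mitochondrial genes was 0.826% ± 0.175 and 0.676% ± 0.110 in the CaMK2a IP after kainic acid and PBS, against 6.98% ± 0.686 and 6.88% ± 0.412 in its inputs. In the PV line it was 2.48% ± 1.08 and 1.67% ± 0.585 in the IP, against 9.08% ± 2.84 and 7.76% ± 2.55 in the inputs. PV replicate 4 stood apart from PV replicates 1 to 3 in all 4 PV groups, so counts and list calls that change with PV replicates 1 to 3 only are given beside the PV results. Levels below are CPM as mean ± SD and changes are log2 fold changes ± SE. Coordinates are those of the deposited tables on mm10 (GRCm38), and gene identifiers are those in the tables. The tagged gene Rpl22 and the astrocyte gene Gfap are in none of the tables and were not analysed here. Some other list members were absent too. Of 22 glutamate receptor genes 15 were present, without the AMPA receptor genes Gria1, Gria2, Gria3 and Gria4 and without Grin2c, Grik1 and Grm7. Results for that list therefore do not cover AMPA receptors. Of 39 potassium and HCN channel genes 32 were present, and of 23 sodium and calcium channel genes 19.

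Kainic acid against PBS in the CaMK2a IP asks which ribosome-bound transcripts of CaMK2a-Cre cells differ 6 h after the drug. Inhba (gene ID 16323, chromosome 13, 16011832 to 16027723, 5 exons), which encodes a subunit of activin A, rose from 25.6 ± 3.94 to 3069.6 ± 607 CPM, or 120.3-fold (n = 3 per group). The immediate early transcription factors Fos (gene ID 14281, chromosome 12, 85473901 to 85477269, 4 exons) and Npas4 (gene ID 225872, chromosome 19, 4984353 to 5001929, 9 exons) rose 116-fold and 115-fold, and Fosb rose 102-fold. The growth factor gene Bdnf (gene ID 12064, chromosome 2, 109674700 to 109727043, 9 exons) rose from 69.7 ± 9.2 to 769 ± 225 CPM. Scg2 (gene ID 20254, chromosome 1, 79434669 to 79440123, 2 exons), a secretogranin of dense-core vesicles, rose from 478 ± 23.6 to 4805 ± 1342 CPM. Rgs2 (gene ID 19735, chromosome 1, 143999338 to 144004149, 5 exons), a regulator of G protein signalling, rose from 72.6 ± 5.61 to 839 ± 213 CPM. Nptx2, a synaptic pentraxin, and Pcsk1, a prohormone convertase, changed by 4.03 ± 0.18 and 3.62 ± 0.28 on the log2 scale. Among the largest rises by rule were also Thbs1, which encodes thrombospondin 1, at 6.80 ± 0.50, Fndc9 at 5.43 ± 0.31, and the Hsp70 chaperone genes Hspa1a at 6.92 ± 0.42 and Hspa1b at 6.59 ± 0.40. Hspa1a and Hspa1b are nearly identical in sequence, so reads can be shared between them and their separate values are uncertain. The largest falls were smaller: Htr5b, a serotonin receptor gene, fell 5.78-fold from 34 ± 4.51 to 5.86 ± 1.38 CPM, the orphan receptor gene Gpr12 fell 4.47-fold, and Tox3, Ankrd63 and Lct fell 4.87-fold, 4.41-fold and 4.36-fold. Kif26b, the sialyltransferase gene St6gal2 and Arhgap12 completed the 8 largest falls at -1.93 ± 0.23, -1.91 ± 0.15 and -1.90 ± 0.13. Among the genes of this paragraph Tox3 had the highest adjusted p = 3.0e-04, and in each of them all 3 kainic acid libraries lay on the same side of all 3 PBS libraries.

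In all, 2111 transcripts rose and 1633 fell of 10663 tested in the CaMK2a IP with edgeR, 828 of the rises and 279 of the falls by at least 2-fold, and the median change of all genes was 0.01. The deposited table of the authors holds 2121 genes higher and 1717 lower at an FDR under 0.05, of which 3491 are among those called here. Leaving out CaMK2a PBS IP replicate 1 gave 1479 rises and 1013 falls, and leaving out replicate 3 gave 1501 and 979. With upper-quartile factors, which shift the median of all genes to -0.09, 1674 transcripts rose and 2276 fell, so the share of rises among called genes went from 56.4% to 42.4%.

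Gene lists fixed beforehand moved as follows in the CaMK2a IP. Of 22 inducible transcription factors 21 rose (median 2.42), and of 26 activity-regulated effectors 25 rose (median 3.46). Camera gave them adjusted p = 1.1e-12 and 2.8e-20. Of 12 inhibitors that act back on MAP kinase signalling 10 rose, such as Errfi1 at 2.86 ± 0.28, Dusp4 at 2.32 ± 0.12 and Spry2 at 2.02 ± 0.14 (camera adjusted p = 3.8e-06). Of 16 neuropeptide precursor genes 13 rose, Npy from 2.47 ± 1.61 to 37.2 ± 15.8 CPM and Sst, also a marker of other interneurons, from 95.1 ± 17.9 to 827 ± 371 CPM (camera adjusted p = 1.2e-06). Of 16 heat shock chaperones 13 rose, or 16 adjusted over the list alone, with Bag3 at 5.15 ± 0.15 (camera adjusted p = 7.4e-09). Of 20 cholesterol synthesis genes 10 rose, or 11 adjusted over the list alone, with Cyp51 at 1.98 ± 0.22 (camera adjusted p = 5.8e-05). Of 17 endoplasmic reticulum stress genes 13 rose, with Hspa5, the lumenal chaperone BiP, from 213 ± 8.37 to 733 ± 168 CPM (camera adjusted p = 2.6e-05). The dense-core granule list had 8 rises and 2 falls of 13. Glycolysis and lactate transport had 10 rises of 21, with the monocarboxylate transporter gene Slc16a1 at 1.89 ± 0.23. Reactive astrocyte genes had 12 rises of 14, and these 3 lists passed (camera adjusted p = 0.0087, 1.8e-04 and 5.3e-06). The falling lists were sodium and calcium channels, with 9 falls of 19 (median -0.41), glutamate receptors, with 7 falls of 15, and GABA receptors, with 6 falls and 2 rises of 14 (camera adjusted p = 0.0015, 0.021 and 0.023). Examples are Scn3a, a sodium channel gene, at -1.15 ± 0.18, and Gabra5 at -0.61 ± 0.08. With an estimated correlation none of these calls held: adjusted p = 0.31 with an estimated correlation for each list of this paragraph up to here. Further lists past the threshold were glucocorticoid-responsive genes, 8 rises of 14 with Cdkn1a at 4.17 ± 0.23, and cytokines and inflammatory genes, 5 rises of 9 with Socs3 at 5.62 ± 0.52. Cytosolic ribosomal proteins had 29 rises of 64 with Rplp0 at 0.69 ± 0.11, and CA1 pyramidal neuron markers 5 falls of 13 with Neurod6 at -1.19 ± 0.09. Their camera adjusted p = 7.7e-04, 0.0087, 1.4e-06 and 0.0087, and adjusted p = 0.38, 0.38, 0.47 and 0.47 with an estimated correlation. Potassium and HCN channels (8 higher and 12 lower of 32), perineuronal net proteins, oxidative phosphorylation and circadian clock genes did not pass (camera adjusted p = 0.36, 0.5, 0.051 and 0.53). Oxidative phosphorylation passed, on the falling side, with relative log expression factors at 0.045 and upper-quartile factors at 0.0097. Among markers of other cells, astrocyte markers had 2 rises of 13 and microglia markers 4 of 12, and neither list passed (camera adjusted p = 0.26 and 0.48).

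**Figure D1:**
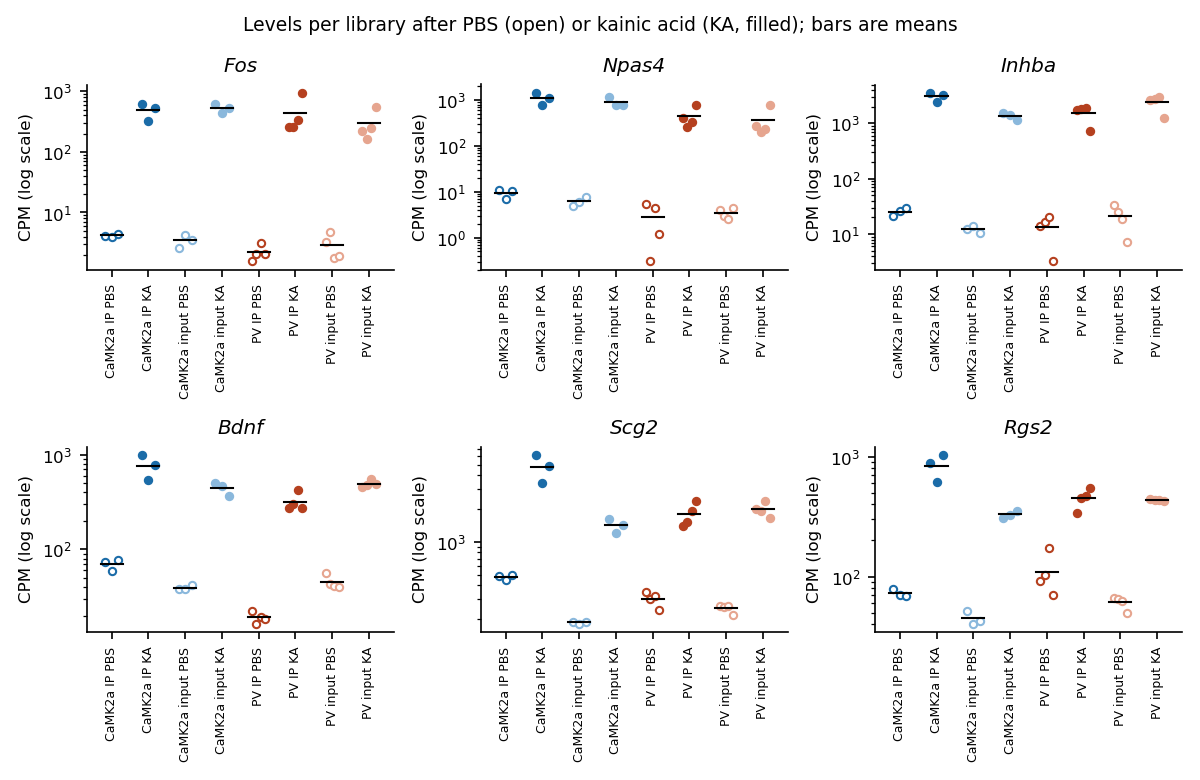
CPM (log axis) of Fos, Npas4, Inhba, Bdnf, Scg2 and Rgs2 in each library of the 8 groups, with open symbols for PBS, filled symbols for kainic acid and bars for group means. In all 4 pairs of groups the kainic acid libraries lie above the PBS libraries.

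The same comparison in the CaMK2a input asks how total CA1 RNA differed. Atf3, a stress-induced transcription factor, rose from 0.667 ± 0.578 to 181 ± 57.5 CPM and Socs3, an inhibitor of cytokine signalling, from 0.733 ± 0.385 to 76.4 ± 27.8 CPM (n = 3 per group). Inhba rose 111-fold, Fos 154-fold, Npas4 149-fold and Fosb 119-fold, and Fndc9 and Hspa1a were also among the largest rises at 6.43 ± 0.26 and 6.10 ± 0.33. Bdnf rose from 39.3 ± 1.98 to 449 ± 72.5 CPM, Scg2 from 184 ± 3.85 to 1412 ± 205 CPM and Rgs2 from 45.1 ± 5.89 to 330.0 ± 22.4 CPM. Nptx2 and Pcsk1 rose 26-fold and 11.3-fold. Ankrd63 fell 6.29-fold, Lct 5.27-fold, Gpr12 4.26-fold, Htr5b 4.01-fold and Magee2 3.9-fold, and Zkscan16, St6gal2 and Syna changed by -1.94 ± 0.18, -1.86 ± 0.16 and -1.78 ± 0.17. All 18 tested reactive astrocyte genes rose, with Ptx3, a secreted pentraxin, from 1.27 ± 0.492 to 66.7 ± 17.2 CPM, and 13 of 15 cytokine and inflammatory genes rose, with Lif from 0.5 ± 0.182 to 42 ± 13.3 CPM (camera adjusted p = 6.0e-14 and 8.8e-09). Inducible transcription factors had 21 rises of 22, effectors 25 of 26 and MAP kinase inhibitors 11 of 12. Neuropeptide precursors had 14 of 18, heat shock chaperones 14 of 16 and cholesterol synthesis genes 13 of 20 (camera adjusted p = 2.0e-22, 4.3e-31, 8.3e-11, 6.8e-09, 8.4e-10 and 2.1e-06). For each list named up to here adjusted p = 0.22 with an estimated correlation. Sodium and calcium channels fell in 9 of 19 members and GABA receptors in 7 of 14, with Scn3a at -1.42 ± 0.17 and Gabra5 at -0.91 ± 0.11 (camera adjusted p = 1.9e-04 and 0.0038, and adjusted p = 0.23 and 0.35 with an estimated correlation). CA2 and CA3 markers fell in 3 of 8 members (camera adjusted p = 0.026, and adjusted p = 0.23 with an estimated correlation). CA1 markers fell in 6 of 13, glutamate receptors in 7 of 15 and potassium and HCN channels in 16 of 32 members, with 1 and 7 rises in the last 2 lists (camera adjusted p = 0.012, 0.0038 and 0.029, and adjusted p = 0.23, 0.22 and 0.28 with an estimated correlation). Astrocyte markers rose in 4 of 13 members (camera adjusted p = 0.037, and adjusted p = 0.23 with an estimated correlation), a list call that ended with upper-quartile factors at 0.068. Further rising lists were endoplasmic reticulum stress (12 of 17), glucocorticoid-responsive genes (12 of 15), glycolysis (8 of 21), ribosomal proteins (12 of 68) and dense-core granule proteins (6 rises and 2 falls of 13). For these camera adjusted p = 8.9e-06, 1.9e-06, 5.9e-04, 0.0038 and 0.012, and adjusted p = 0.23, 0.22, 0.32, 0.58 and 0.22 with an estimated correlation. In the CaMK2a input 2180 transcripts rose and 1773 fell of 11287 tested, and with upper-quartile factors 1896 and 2240. Inputs of the same replicate number were weakly alike in their deviations from group means (r = 0.12, 0.11 and 0.29 for replicates 1, 2 and 3). PBS input replicate 1 was closest to kainic acid input replicate 2. With replicate number as a block of pairs, an alternative set beforehand, there were 2376 rises and 2109 falls. In simulated data of this comparison 17 of 160 calls were false with the block (10.6%) and 5 of 141 in data simulated and fitted without it (3.55%).

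Kainic acid against PBS in the PV IP puts the same question to PV-Cre cells. Fosb rose from 3.21 ± 1.51 to 905 ± 462 CPM, Fos from 2.21 ± 0.648 to 446 ± 331, Npas4 from 2.81 ± 2.41 to 448 ± 236 and Inhba from 13.6 ± 7.35 to 1534 ± 549.9 CPM (n = 4 per group). Bdnf rose 16.6-fold, Nptx2 25.4-fold, Pcsk1 12.1-fold, Scg2 5.91-fold and Rgs2 4.12-fold. The neurotensin gene Nts rose 36.1-fold, Osmr, the oncostatin M receptor gene, 31-fold, Fndc9 79.9-fold and Hspa1a 35.8-fold. Magee2 fell from 50.8 ± 26.1 to 13.1 ± 3.75 CPM, and Cecr6 and Kif26b changed by -1.75 ± 0.35 and -1.58 ± 0.30, with adjusted p = 0.003, 0.0053 and 0.0041. The other 5 of the 8 largest falls were Etaa1 at -1.56 ± 0.41, Fbll1 at -1.67 ± 0.42, Mrgpre at -1.77 ± 0.48, Olfml2b at -1.58 ± 0.42 and Zfp605 at -1.58 ± 0.38. All 5 calls ended without PV PBS IP replicate 1 and without PV kainic acid IP replicate 1. They also ended without PBS IP replicate 2 (Etaa1, Fbll1, Mrgpre), PBS IP replicate 3 (Etaa1, Mrgpre, Olfml2b, Zfp605), PBS IP replicate 4 (Mrgpre), kainic acid IP replicate 2 (Fbll1, Mrgpre, Olfml2b, Zfp605), kainic acid IP replicate 3 (Etaa1, Fbll1, Mrgpre, Olfml2b) and kainic acid IP replicate 4 (Etaa1). Over single libraries left out the values ran from -1.92 to -1.34 for Etaa1, -2.01 to -1.43 for Fbll1, -2.00 to -1.48 for Mrgpre, -1.83 to -1.25 for Olfml2b and -1.81 to -1.32 for Zfp605, and with PV replicates 1 to 3 only Etaa1 (-1.47) and Mrgpre (-1.97) did not pass. Of 22 inducible transcription factors 21 rose (median 3.74), of 26 effectors 23 and of 12 MAP kinase inhibitors 8. These 3 lists had camera adjusted p = 4.2e-37, 4.0e-51 and 6.3e-17, and adjusted p = 0.022, 0.0032 and 0.0073 with an estimated correlation. Glucocorticoid-responsive genes rose in 7 of 15 members, with Mt2, a metallothionein gene, at 1.84 ± 0.23, cytokine and inflammatory genes in 9 of 14 and reactive astrocyte genes in 12 of 17. Here camera gave adjusted p = 1.6e-07, 8.1e-12 and 6.7e-14, and adjusted p = 0.022, 0.022 and 0.028 with an estimated correlation. Further rising lists were neuropeptide precursors (9 of 18, with Sst, a marker of other interneurons, at 1.86 ± 0.17) and dense-core granule proteins (4 of 13). So were heat shock chaperones (6 of 16, or 9 adjusted over the list alone), endoplasmic reticulum stress genes (2 of 17, or 5 adjusted over the list alone), cholesterol synthesis genes (3 of 20, or 6 adjusted over the list alone) and glycolysis genes (3 of 20). Their camera adjusted p = 1.9e-10, 2.7e-05, 9.3e-09, 5.9e-04, 0.0051 and 0.0095, and adjusted p = 0.065, 0.15, 0.15, 0.4, 0.12 and 0.62 with an estimated correlation. Other interneuron class markers rose in 2 of 12 members (median 0.29), and oxidative phosphorylation genes had a median of -0.20 with camera direction down (camera adjusted p = 0.02 and 0.0038, and adjusted p = 0.12 and 0.63 with an estimated correlation). Glycolysis genes did not pass with PV replicates 1 to 3 only (adjusted p = 0.50), whereas PV interneuron and general interneuron markers then passed on the falling side (adjusted p = 0.0062 and 0.021).

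In all, 450 transcripts rose and 89 fell of 11107 tested in the PV IP, where the common coefficient of biological variation was 44.3%, against 14.8% in the CaMK2a IP. With PV replicates 1 to 3 only 577 rose and 178 fell, and with a term for replicate 4 the counts were 681 and 250. DESeq2, the replicate block and the fit to all groups of the line also raised the count of falls, as given in the closing part. The count of falls moved to 30, 38 and 37 without PV PBS IP replicate 1, 2 or 3, to 46, 49 and 42 without PV kainic acid IP replicate 1, 2 or 3, and to 164 without PV kainic acid IP replicate 4. In a test on simulated data of this size 77.3% of 4-fold and 31.3% of 2-fold changes were recovered, against 92.4% and 58.2% in the CaMK2a IP. These rates hold for the simulated number of changed genes and can differ in the data.

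In the PV input, Inhba rose from 21.4 ± 11.2 to 2415 ± 793 CPM, Npas4 107-fold, Fos 102-fold, Fosb 84.8-fold and Fndc9 60.1-fold (n = 4 per group). Ptx3 changed by 5.51 ± 0.53, the matricellular gene Cyr61 by 4.93 ± 0.30 and Hspa1b by 4.81 ± 0.54. Bdnf rose 10.9-fold, Nptx2 19.5-fold, Pcsk1 10.7-fold, Scg2 7.93-fold and Rgs2 7.12-fold. Dsp, a desmosome gene used as a dentate granule cell marker, fell from 35 ± 5.31 to 4.53 ± 4.51 CPM, Ankrd63 fell 4.87-fold, Gpr12 4.57-fold, Magee2 3.84-fold, Lct 3.11-fold, Zkscan16 3.17-fold and the neuronal transcription factor gene Neurod6 3.31-fold. Fn3k, at -1.62 ± 0.30, lost its call when all groups of the line were fitted together (log2 fold change -1.65). All 18 reactive astrocyte genes tested rose, 14 of 16 cytokine and inflammatory genes, 20 of 22 inducible transcription factors and 8 of 16 heat shock chaperones. These lists had camera adjusted p = 2.7e-17, 1.7e-14, 1.6e-24 and 3.1e-06, and adjusted p = 0.095, 0.06, 0.095 and 0.12 with an estimated correlation. Effectors rose in 24 of 26 members and MAP kinase inhibitors in 9 of 12, with camera adjusted p = 6.6e-35 and 1.5e-12, and adjusted p = 0.022 and 0.036 with an estimated correlation. Sodium and calcium channels fell in 4 of 19 members, or 7 adjusted over the list alone, with Scn1a at -0.63 ± 0.14 (camera adjusted p = 7.5e-04, and adjusted p = 0.11 with an estimated correlation). CA1 markers fell in 3 of 13 members, glutamate receptors in 3 of 15 and potassium and HCN channels in 8 of 32, with 4 rises in the last list (camera adjusted p = 0.019, 0.032 and 0.032, and adjusted p = 0.23, 0.12 and 0.36 with an estimated correlation). Neuropeptide precursors rose in 10 of 17, glucocorticoid-responsive genes in 8 of 15, endoplasmic reticulum stress genes in 5 of 17, cholesterol synthesis genes in 6 of 20 and dense-core granule proteins in 4 of 13. Ribosomal proteins had a median of 0.23 with camera direction up. For these 6 lists camera adjusted p = 3.1e-10, 1.0e-04, 2.1e-05, 4.5e-04, 0.0027 and 0.022, and adjusted p = 0.11, 0.11, 0.11, 0.26, 0.095 and 0.66 with an estimated correlation. In the PV input 915 transcripts rose and 374 fell of 11145 tested. With replicate number as a block, though only replicate 4 clearly pairs, 1835 rose and 1590 fell. GABA receptors and oxidative phosphorylation then also passed with camera on the falling side and glycolysis on the rising (adjusted p = 0.049, 0.035 and 0.046). With PV replicates 1 to 3 only 1608 rose and 1150 fell, potassium and HCN channels and ribosomal proteins no longer passed (adjusted p = 0.10 and 0.096), and oxidative phosphorylation passed on the falling side (0.016). With a term for replicate 4 the counts were 1866 and 1596, and the lists that passed with the block passed here too (0.041, 0.036 and 0.047). The count of falls moved to 198, 196 and 213 without PV PBS input replicate 1, 2 or 3, to 209 without PV kainic acid input replicate 3 and to 616 without PV kainic acid input replicate 4.

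**Figure D2:**
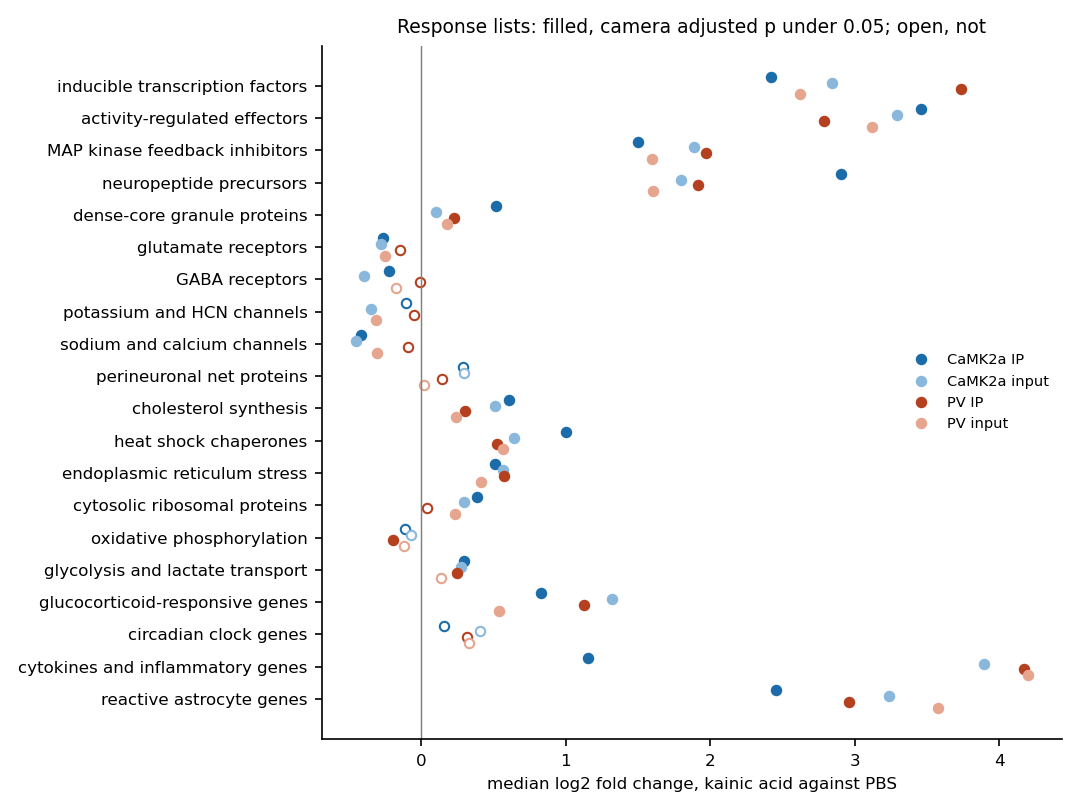
Median log2 fold change after kainic acid of the tested members of 20 response lists in the IP and input of both lines, filled where the camera adjusted p is under 0.05 at the preset correlation. Inducible transcription factors, activity-regulated effectors and reactive astrocyte genes have positive medians in all 4 comparisons, and sodium and calcium channels negative medians.

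Setting the IPs of both lines side by side asks how far the responses overlap. Of 10430 transcripts tested in both, 409 rose in both IPs, where 85.8 would be expected if the calls were independent. In both IPs 59 fell, against 13 expected, and no transcript past the edgeR threshold in both went in opposite directions. Fos, Fosb, Npas4, Inhba, Bdnf, Nptx2, Pcsk1, Scg2 and Rgs2 are all among those that rose in both. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.717. Between the IP and the input of the CaMK2a line 1523 transcripts rose in both, 1083 fell in both and 6 were called in opposite directions. Between the IP and the input of the PV line 399 rose in both and 42 fell in both, with 36.4 and 2.93 expected.

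**Figure D3:**
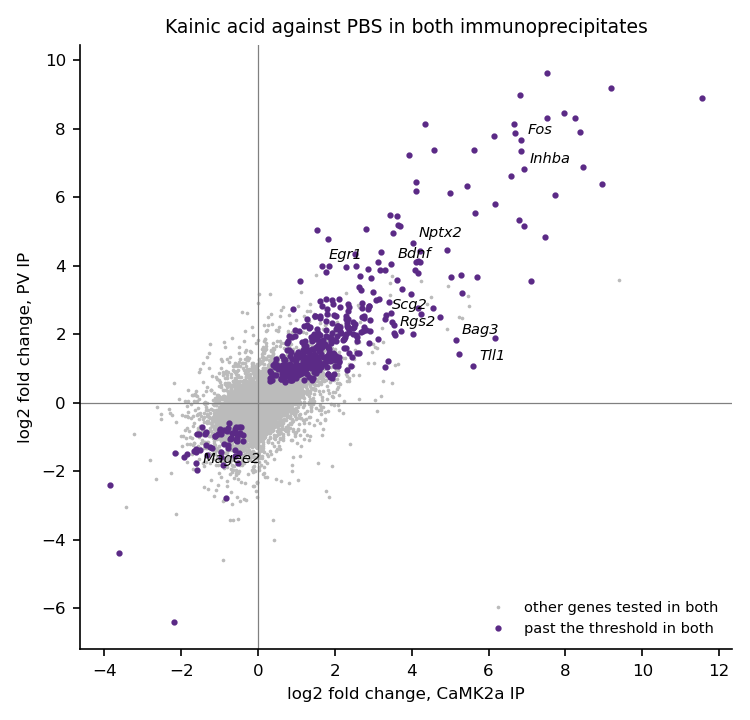
Log2 fold change after kainic acid of 10430 transcripts in the CaMK2a IP (horizontal) and in the PV IP (vertical), purple where past the threshold in both. The 409 transcripts that rose in both and the 59 that fell in both lie in the upper right and lower left.

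Whether the response itself differed was tested as a difference of effects. Within the CaMK2a line, Unc5b, a netrin receptor gene, rose more in the IP than in the input by 1.95 ± 0.24, and Ptgs1, which encodes cyclooxygenase 1, by 2.32 ± 0.29 (n = 3 per group). Klf3, a repressor of the Kruppel-like family, changed by -1.55 ± 0.17, the thrombomodulin gene Thbd by -1.62 ± 0.19 and the inositol trisphosphate kinase gene Itpkb by -1.91 ± 0.26, each lower in the IP effect than in the input effect. Klf3 changed by -1.86 in the IP, whereas Thbd and Itpkb rose in the input, at 1.57 and 1.36, and did not pass in the IP. Further differences past the threshold were Npy at 2.52 ± 0.44, the endothelin receptor gene Ednrb at 1.76 ± 0.29, Rgs10 at 1.48 ± 0.25, Sh3bp4 at -1.33 ± 0.23 and Cebpd at -2.00 ± 0.35. Each of these 5 calls ended without PBS IP replicate 1 or 3, kainic acid IP replicate 3, PBS input replicate 1 or 3 or kainic acid input replicate 3 of the CaMK2a line. Without kainic acid input replicate 1 or PBS input replicate 2 all but Ednrb lost their calls, without PBS IP replicate 2 Sh3bp4 and Cebpd, and without kainic acid input replicate 2 Npy. Over single libraries left out the values ran from 2.15 to 3.11 for Npy, 1.64 to 2.05 for Ednrb, 1.38 to 1.62 for Rgs10, -1.54 to -1.14 for Sh3bp4 and -2.29 to -1.75 for Cebpd. Fos, Npas4, Inhba, Bdnf, Scg2 and Rgs2 did not pass, with differences of -0.45 ± 0.38, -0.41 ± 0.36, 0.08 ± 0.24, -0.09 ± 0.26, 0.35 ± 0.23 and 0.62 ± 0.22. Inducible transcription factors (median -0.35) and MAP kinase inhibitors (median -0.49) rose less in the IP than in the input, heat shock chaperones (median 0.31) and other interneuron class markers (median 0.51) more. Their tests gave camera adjusted p = 0.0036, 0.0012, 0.005 and 0.0012, and adjusted p = 0.86, 0.86, 0.86 and 0.094 with an estimated correlation. In all, 5 differences were positive and 7 negative of 11623 tested (984 at an unadjusted p under 0.05, where chance gives 581), more of both with DESeq2 (counts in the closing part), and 26 and 31 with the replicate block. With that block neuropeptide precursors (adjusted p = 0.036), potassium and HCN channels (0.036), oxidative phosphorylation (0.030), glucocorticoid-responsive genes (0.036), cytokines (0.048) and reactive astrocyte genes (0.036) passed too. The total of 12 moved to 6, 5 and 6 without CaMK2a PBS IP replicate 1 or 3 or CaMK2a kainic acid IP replicate 3, to 5, 7 and 5 without CaMK2a PBS input replicate 1, 2 or 3, to 8 and 5 without CaMK2a kainic acid input replicate 1 or 3, and to 63, 43 and 21 without CaMK2a kainic acid IP replicate 1 or 2 or CaMK2a kainic acid input replicate 2.

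Within the PV line, Vmp1, a gene of autophagy, rose more in the IP than in the input by 1.45 ± 0.21, and Tll1, a metalloprotease gene, changed by -2.47 ± 0.32 (n = 4 per group). Fam43a, at -1.70 ± 0.28, lost its call in turn without 9 of the 16 libraries, with values of -1.87 to -1.60, and with PV replicates 1 to 3 only. Those 9 were PV PBS IP replicates 2 and 3, PV kainic acid IP replicates 2 and 3, PV PBS input replicates 3 and 4, and PV kainic acid input replicates 1, 3 and 4. These 3 genes were all that passed of 11862 tested (504 at an unadjusted p under 0.05, where chance gives 593); the replicate block gave 4 positive and 5 negative, PV replicates 1 to 3 gave 4 and 6, and a term for replicate 4 gave 2 and 5. Inducible transcription factors had a median difference of 0.62 (camera adjusted p = 5.2e-05, and adjusted p = 0.71 with an estimated correlation). GABA receptors, potassium and HCN channels, sodium and calcium channels, cytosolic ribosomal proteins and CA1 markers passed with the block of pairs (adjusted p = 0.020, 0.020, 0.013, 0.020 and 0.028), and all but CA1 markers with a term for replicate 4 (0.025, 0.032, 0.022 and 0.022). With PV replicates 1 to 3 only CA1 markers passed on the positive side, and oxidative phosphorylation and general interneuron markers on the negative (adjusted p = 1.2e-04, 0.030 and 0.047).

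Between the IPs, Tll1 rose in the CaMK2a IP from 1.16 ± 0.717 to 52.8 ± 19.2 CPM and the difference from its PV effect was 4.51 ± 0.49. Bag3, a chaperone cofactor gene, rose from 5.83 ± 0.543 to 205 ± 30.2 CPM with a difference of 3.31 ± 0.32 (n = 3 and 4 per group). Both also rose in the PV IP, Tll1 by 1.06 and Bag3 by 1.83 on the log2 scale. Lbh, Cgref1 and Ubash3b also had positive differences, at 2.25 ± 0.36, 2.17 ± 0.34 and 2.10 ± 0.35, and Klf3 a negative one at -1.76 ± 0.29. Their calls ended without CaMK2a PBS IP replicate 1 or 2, for Cgref1, Ubash3b and Klf3 also without replicate 3, and for Cgref1 and Klf3 also without CaMK2a kainic acid IP replicate 3, with values of 1.80 to 2.58 for Lbh, 1.93 to 2.33 for Cgref1, 1.70 to 2.33 for Ubash3b and -1.93 to -1.64 for Klf3. March4, at -1.43 ± 0.27, and the immediate early gene Egr1, at -2.33 ± 0.44, both with adjusted p = 0.043, lost their calls without any of CaMK2a PBS IP replicates 1 to 3, CaMK2a kainic acid IP replicates 2 and 3, PV PBS IP replicates 1 and 4 and PV kainic acid IP replicate 3. The March4 call also ended without CaMK2a kainic acid IP replicate 1 or PV kainic acid IP replicate 2 (-1.56 to -1.33 over single libraries left out). The Egr1 call also ended without PV PBS IP replicate 2 or 3 or PV kainic acid IP replicate 1 (-2.77 to -2.02), and with upper-quartile factors. Fos, Fosb, Npas4, Inhba, Bdnf, Scg2 and Rgs2 did not pass with edgeR, with differences of -0.80 ± 0.57, -1.45 ± 0.54, -0.48 ± 0.68, 0.09 ± 0.55, -0.59 ± 0.29, 0.76 ± 0.28 and 1.49 ± 0.35, and Rgs2 passed with DESeq2 (1.45) and with PV replicates 1 to 3 only (1.69). Inducible transcription factors rose less in the CaMK2a IP (median -0.80), as did cytokine and inflammatory genes (median -1.66), whereas heat shock chaperones (median 0.54) and cholesterol synthesis genes (median 0.49) rose more. The tests gave camera adjusted p = 6.9e-10, 6.3e-05, 5.4e-07 and 8.6e-04, and adjusted p = 0.23, 0.23, 0.25 and 0.23 with an estimated correlation. MAP kinase inhibitors, GABA receptors, sodium and calcium channels and ribosomal proteins had medians of -0.13, -0.22, -0.14 and 0.38. For them the tests gave camera adjusted p = 0.0017, 0.011, 0.035 and 0.0026, and adjusted p = 0.23, 0.23, 0.23 and 0.81 with an estimated correlation. Reactive astrocyte genes had a positive median of 0.25, while the camera direction was down (adjusted p = 0.01, and 0.52 with an estimated correlation). That call ended with the replicate block (0.066) and with PV replicates 1 to 3 only (0.10). Circadian clock genes and CA1 markers passed on the negative side with the block (adjusted p = 0.028 each) and with a term for replicate 4 (0.016 and 0.040). With PV replicates 1 to 3 only CA1 markers passed on the negative side, and glycolysis, endoplasmic reticulum stress and oxidative phosphorylation on the positive (adjusted p = 0.0011, 0.0012, 0.021 and 0.029). In all, 8 differences were positive and 3 negative of 11781 tested (719 at an unadjusted p under 0.05, where chance gives 589), more of both with DESeq2 (counts in the closing part), 39 and 31 with PV replicates 1 to 3 only, and 17 and 11 with a term for replicate 4. The total of 11 moved to 4, 2 and 4 without CaMK2a PBS IP replicate 1, 2 or 3, to 6 without CaMK2a kainic acid IP replicate 3 and to 24 without PV kainic acid IP replicate 4. The line, the RNA amount and the number of pooled mice differ together here.

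**Figure D4:**
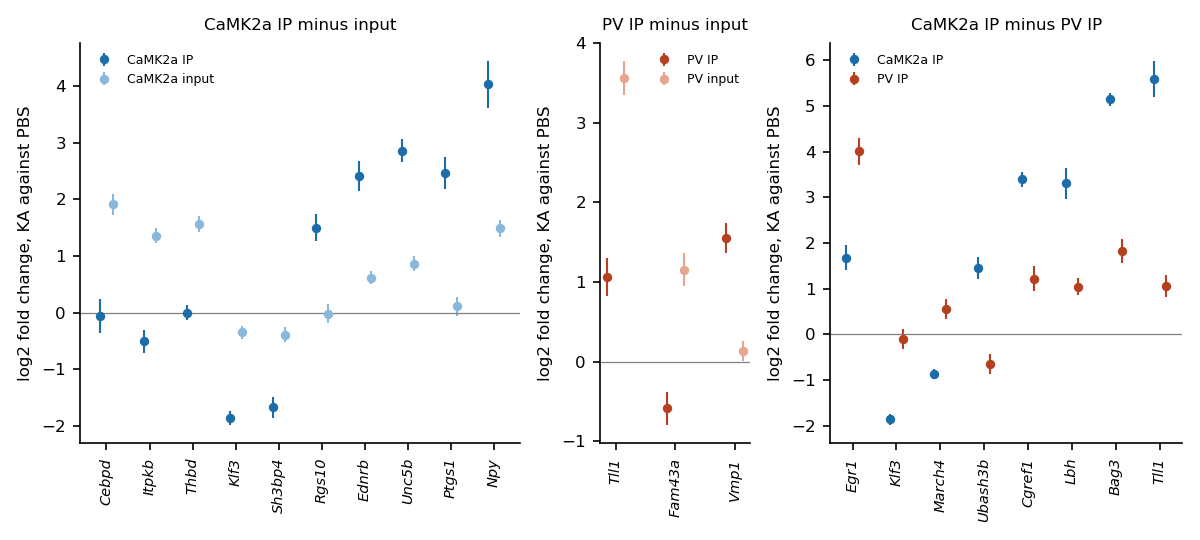
Log2 fold change after kainic acid with SE, in the 2 groups of libraries compared, of the genes whose effects differ by the rule, in 3 panels: CaMK2a IP and input, PV IP and input, and the IPs of both lines. Tll1 and Bag3 show the widest gaps between the IPs, at 4.51 and 3.31.

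IP against input asks which transcripts the pulled ribosomes hold relative to the whole tissue. In the CaMK2a line after PBS, Slc32a1 and Pvalb, genes of inhibitory neurons, were 11.7-fold and 8.41-fold lower in the IP, and Gad1, a GABA-synthesizing enzyme gene, 6.01-fold lower (n = 3 per group). The glial gene Apoe was 18.2-fold lower at 30.6 ± 5.27 against 548 ± 28.8 CPM, Mfge8 21.3-fold, Gpr37l1 18.3-fold and the microglial receptor gene Csf1r 18-fold lower. Vtn, Slc38a3, S100a16 and Cd9 had values of -4.40 ± 0.18, -4.10 ± 0.25, -4.05 ± 0.22 and -3.96 ± 0.21. The myelin gene Mbp, the microglial gene Cx3cr1, the endothelial gene Cldn5 and the interneuron gene Sst were lower at -2.21 ± 0.16, -2.76 ± 0.25, -3.11 ± 0.41 and -2.83 ± 0.11. Camk2a itself was 1.15-fold higher at 0.20 ± 0.06, a call that ended without CaMK2a PBS input replicate 1 and with upper-quartile factors (0.08), and the vesicular glutamate transporter gene Slc17a7 was lower at -0.41 ± 0.07. The largest ratios were Hmgn5 at 8.17-fold, Mpdz, a scaffold gene, at 7.56-fold, Arhgap12 at 6.01-fold, and Ccdc55, Cep83, Cep290, Esf1 and Grem1 at 2.58 ± 0.10, 2.52 ± 0.12, 2.48 ± 0.16, 2.39 ± 0.16 and 2.38 ± 0.19. CA1 pyramidal neuron markers were higher in 11 of 13 members (median 0.79), and every tested astrocyte (13), oligodendrocyte (10), oligodendrocyte precursor (7), microglia (14) and endothelial (12) marker was lower, with medians of -2.66, -2.42, -2.64, -3.36 and -2.73. Camera adjusted p = 1.9e-04 for CA1 and 9.5e-11, 4.0e-07, 8.2e-05, 3.6e-08 and 8.2e-05 for the others, and adjusted p = 0.18, 0.18, 0.21, 0.18, 0.18 and 0.18 with an estimated correlation. PV interneuron markers were lower in 8 of 9, general interneuron markers in 10 of 11, other interneuron class markers in 9 of 11, mural cell markers in 9 of 10, choroid plexus, ependymal and meningeal markers in 8 of 10 and red blood cell markers in 5 of 5. For these camera adjusted p = 0.0011, 2.7e-05, 0.0011, 0.0014, 0.028 and 0.017, and adjusted p = 0.18, 0.18, 0.18, 0.18, 0.37 and 0.37 with an estimated correlation. Reactive astrocyte genes were lower in 10 of 13, neuropeptide precursors in 10 of 15 and glucocorticoid-responsive genes in 9 of 15, and heat shock chaperones were higher in 10 of 15 and circadian clock genes in 11 of 17. Their camera adjusted p = 0.012, 0.039, 0.011, 0.003 and 0.033, and adjusted p = 0.18, 0.18, 0.21, 0.18 and 0.21 with an estimated correlation. With upper-quartile factors neuropeptide precursors and choroid plexus, ependymal and meningeal markers no longer passed (adjusted p = 0.069 and 0.052) and glycolysis passed on the lower side (0.020), as it did with relative log expression factors (0.047). Dentate granule cell markers and CA2 and CA3 markers did not pass (camera adjusted p = 0.38 and 0.058). In all, 3648 transcripts were higher and 3541 lower of 11190 tested, and with the lysate pools as a block of pairs 3606 and 3481, where glycolysis also passed on the lower side (adjusted p = 0.049). IP and input of the same number were barely alike in their deviations from group means here (r = -0.021, 0.046 and 0.082). Upper-quartile factors shift the median of all genes to -0.13 here and to -0.15 after kainic acid, with 2994 higher and 4196 lower here and 2209 and 3344 after kainic acid.

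After kainic acid the CaMK2a IP against its input gave 2689 transcripts higher and 2860 lower of 11076, and 2967 and 3102 with the block of pairs. Slc32a1 was 14.9-fold lower, Pvalb 15.5-fold, Gad1 5.03-fold, Mbp 5.77-fold and Cx3cr1 6.42-fold lower (n = 3 per group). Vtn, Notch1, the complement receptor gene C5ar1, Agt, Pglyrp1, Csf1r and Lcn2 were the other largest differences on the lower side, from -4.09 ± 0.22 for Vtn to -3.76 ± 0.41 for Lcn2. Hmgn5, Mpdz, Cep290, Grem1, Ccdc55, Dnajc2, Dnttip2 and Zfp37 led the higher side, from 3.29 ± 0.36 for Hmgn5 to 2.42 ± 0.24 for Zfp37. Camk2a did not pass, at 0.17 ± 0.12 (adjusted p = 0.26), and Slc17a7 was lower at -0.55 ± 0.15. Sst was lower at -0.94 ± 0.31, and its call ended without CaMK2a kainic acid input replicate 1 or 3 or CaMK2a kainic acid IP replicate 3 (-1.19 to -0.61 over single libraries left out) and with DESeq2 (-0.93). All 18 tested reactive astrocyte genes were lower in the IP (median -2.00), as were 14 of 16 cytokine and inflammatory genes (median -2.73) and all 13 astrocyte markers (median -2.18). The 3 lists had camera adjusted p = 2.0e-06, 4.3e-04 and 1.8e-09, and adjusted p = 0.36, 0.37 and 0.33 with an estimated correlation. GABA receptors were higher in 11 of 14 members and CA1 markers in 7 of 13, with camera adjusted p = 8.2e-05 and 0.0018, and adjusted p = 0.33 and 0.37 with an estimated correlation. Potassium and HCN channels were higher in 18 of 32, sodium and calcium channels in 10 of 19 and heat shock chaperones in 10 of 16 (camera adjusted p = 0.0014, 0.021 and 7.2e-04, and adjusted p = 0.33, 0.4 and 0.4 with an estimated correlation). All tested oligodendrocyte (10), oligodendrocyte precursor (7), microglia (14), endothelial (12) and red blood cell (5) markers were lower, and 8 of 10 mural cell markers (camera adjusted p = 2.6e-06, 4.1e-05, 9.5e-08, 1.0e-05, 0.0048 and 7.2e-04, and adjusted p = 0.36, 0.3, 0.3, 0.3, 0.37 and 0.3 with an estimated correlation). PV interneuron markers were lower in 7 of 9, general interneuron markers in 10 of 12 and other interneuron class markers in 9 of 12 (camera adjusted p = 0.0021, 3.1e-05 and 0.012, and adjusted p = 0.3, 0.36 and 0.3 with an estimated correlation). So were 10 of 18 neuropeptide precursors, 8 of 12 perineuronal net, 11 of 20 cholesterol synthesis, 33 of 66 ribosomal protein, 24 of 56 oxidative phosphorylation and 12 of 15 glucocorticoid-responsive genes. For these 6 lists camera adjusted p = 0.031, 4.4e-04, 0.0021, 5.6e-04, 0.0038 and 7.5e-04, and adjusted p = 0.4, 0.3, 0.4, 0.54, 0.67 and 0.37 with an estimated correlation. With the block of pairs dense-core granule proteins passed on the higher side and choroid plexus, ependymal and meningeal markers on the lower (adjusted p = 0.037 and 5.6e-04).

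In the PV line after PBS, Pvalb, the gene whose promoter drives Cre, was 13-fold higher in the IP at 155 ± 29.8 against 11.8 ± 6.4 CPM (n = 4 per group). Gad1 (gene ID 14415, chromosome 2, 70561768 to 70602014, 20 exons) was 6.08-fold and Slc32a1 (gene ID 22348, chromosome 2, 158610758 to 158615747, 2 exons) 3.81-fold higher, and the PV cell genes Syt2, a synaptotagmin, and Akr1c18 were 16.6-fold and 19.8-fold higher. Sptan1, which encodes a spectrin, reached 19613 ± 6359 CPM against 588 ± 46.4, and Ppp1r9a, which encodes neurabin, 9244 ± 3208 against 308 ± 81.2. Mmp2, Mpdz, Limch1 and Actn2 were at 4.98 ± 0.42, 4.49 ± 0.19, 4.33 ± 0.27 and 4.17 ± 0.34. Camk2a and Slc17a7 were lower at -0.83 ± 0.13 and -1.16 ± 0.28, while Camk2a still stood at 4447 ± 576 CPM in the PV IP. Sst was lower at -0.97 ± 0.13 and Cx3cr1 at -1.17 ± 0.23, and Mbp and Cldn5 did not pass, at 0.07 ± 0.24 and -1.03 ± 0.70. The mitochondrial transcripts mt-Co1_COX1 and mt-Cytb_CYTB, with Ctss, Clic6, Col9a3, Vtn, Apoe and Gsta4, were the largest differences on the lower side, at -2.80 ± 0.27 for mt-Co1_COX1 and -2.44 ± 0.42 for Ctss. All 9 PV interneuron markers tested were higher (median 3.03), as were 10 of 12 general interneuron markers, and other interneuron class markers were lower in 5 of 12, CA1 markers in 11 of 13 and astrocyte markers in 11 of 13. Camera adjusted p = 1.2e-12, 1.8e-11, 6.8e-04, 3.9e-07 and 1.5e-09, and adjusted p = 0.0058, 0.0058, 0.043, 0.064 and 0.0058 with an estimated correlation. Inducible transcription factors were lower in 5 of 19, with Egr1 at -1.18 ± 0.17, microglia markers in 9 of 14 and cholesterol synthesis genes in 8 of 20, and oxidative phosphorylation genes higher in 8 of 56. Their lists had camera adjusted p = 7.8e-04, 3.9e-07, 7.2e-05 and 4.4e-05, and adjusted p = 0.069, 0.12, 0.043 and 0.37 with an estimated correlation. Effectors were lower in 6 of 25, neuropeptide precursors in 5 of 16 and glucocorticoid-responsive genes in 4 of 15, and reactive astrocyte genes had a median of -0.83 (camera adjusted p = 0.047, 0.038, 5.2e-04 and 0.049, and adjusted p = 0.13, 0.32, 0.043 and 0.14 with an estimated correlation). Oligodendrocyte markers were lower in 4 of 10, oligodendrocyte precursor in 3 of 7, endothelial in 3 of 11, mural cell in 3 of 10, choroid plexus, ependymal and meningeal in 5 of 11 and CA2 and CA3 markers in 1 of 8. For these camera adjusted p = 0.015, 0.041, 0.0027, 0.0035, 0.0031 and 0.01, and adjusted p = 0.31, 0.22, 0.13, 0.12, 0.14 and 0.14 with an estimated correlation. With upper-quartile factors effectors, neuropeptide precursors, reactive astrocyte genes and oligodendrocyte precursor markers no longer passed (adjusted p = 0.053, 0.053, 0.065 and 0.050), nor did reactive astrocyte genes with relative log expression factors (0.051). Among ion channels Kcnc1 and Kcnc2, fast potassium channel genes of PV cells, were higher at 2.03 ± 0.13 and 1.88 ± 0.13, while the list of 32 potassium and HCN channels did not pass (camera adjusted p = 0.49). In all, 1183 transcripts were higher and 894 lower of 11204, 1019 and 1104 with upper-quartile factors, and 1771 and 1599 with the lysate pools as a block of pairs. With PV replicates 1 to 3 only 1431 and 1168 passed, with a term for replicate 4 1855 and 1518, and without PV PBS input replicate 2 839 and 581. With the block, neuropeptide precursors and reactive astrocyte genes no longer passed (adjusted p = 0.069 and 0.16), and dense-core granule proteins and glutamate receptors passed on the lower side (0.035 and 0.011). Effectors and reactive astrocyte genes no longer passed with PV replicates 1 to 3 only (adjusted p = 0.083 and 0.075), and dense-core granule proteins, glutamate receptors and cytokines passed on the lower side (0.046, 0.021 and 0.039). With a term for replicate 4 neuropeptide precursors, reactive astrocyte genes and oligodendrocyte precursor markers no longer passed (adjusted p = 0.059, 0.097 and 0.059), and glutamate receptors passed (0.013). Of 10950 transcripts tested in both lines after PBS, 573 were higher in both IPs, 489 lower in both and 547 called in opposite directions.

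After kainic acid the PV IP held Pvalb 19.2-fold, Syt2 16.5-fold, the potassium channel gene Kcng4 17.4-fold and Gad1 5.77-fold above its input, with Slc32a1 at 2.22 ± 0.25 (n = 4 per group). Ppp1r9a, Sptan1, Mpdz, Ift27 and Akr1c18 were the other largest ratios, at 14.1-fold, 13.6-fold, 13-fold, 12.1-fold and 11.5-fold. Ctss was 6.03-fold lower, mt-Co1_COX1 5.35-fold, Csf1r 4.7-fold and Apod 4.1-fold, and Fkbp9, Ptprz1, Slc39a12 and Apoe were at -2.10 ± 0.34, -2.01 ± 0.20, -1.99 ± 0.42 and -1.99 ± 0.45. Mbp, Sst and Cldn5 did not pass, at -0.09 ± 0.22, -0.34 ± 0.17 and 0.23 ± 0.90. Camk2a did not pass, at -0.48 ± 0.20, and was called lower with the block at -0.53. Slc17a7 was lower at -0.86 ± 0.23, a call that ended without PV kainic acid input replicate 3 or PV kainic acid IP replicate 1, 2 or 3 (-0.98 to -0.52). Cx3cr1 was lower at 16.3 ± 6.05 against 32.8 ± 1.72 CPM, a call that ended without any of the 4 PV kainic acid input libraries or PV kainic acid IP replicate 1 or 2 (-1.17 to -0.78). PV interneuron markers were higher in 8 of 9, general interneuron markers in 10 of 12, and astrocyte markers were lower in 8 of 13, CA1 markers in 2 of 13 and reactive astrocyte genes in 4 of 18. Camera adjusted p = 8.4e-13, 8.4e-11, 3.3e-09, 1.7e-04 and 4.3e-04, and adjusted p = 0.075, 0.075, 0.065, 0.12 and 0.34 with an estimated correlation. Microglia markers were lower in 7 of 14, oligodendrocyte in 3 of 10, oligodendrocyte precursor in 3 of 7, endothelial in 1 of 11, mural cell in 2 of 10 and choroid plexus, ependymal and meningeal markers in 3 of 10. For these camera adjusted p = 8.8e-08, 0.0026, 0.042, 0.0049, 0.0039 and 6.1e-04, and adjusted p = 0.065, 0.13, 0.17, 0.12, 0.13 and 0.12 with an estimated correlation. Other interneuron class markers were lower in 4 of 13, cholesterol synthesis in 6 of 20, glucocorticoid-responsive in 3 of 15 and cytokine and inflammatory genes in 2 of 18 (camera adjusted p = 0.0095, 1.6e-05, 0.0049 and 0.025, and adjusted p = 0.12, 0.17, 0.19 and 0.49 with an estimated correlation). GABA receptors were higher in 5 of 14 and oxidative phosphorylation genes in 2 of 56 (camera adjusted p = 0.023 and 0.0026, and adjusted p = 0.35 and 0.6 with an estimated correlation). In all, 767 transcripts were higher and 460 lower of 11205, and with upper-quartile factors 651 and 627. With the lysate pools as a block of pairs 1313 and 1082 passed, with PV replicates 1 to 3 only 1064 and 642 and with a term for replicate 4 1343 and 1009. Without PV kainic acid input replicate 1, 2 or 3 the counts were 511 and 243, 579 and 299, and 486 and 234. With the block of pairs activity-regulated effectors passed on the lower side (adjusted p = 0.018) and GABA receptors no longer passed (0.070), as with a term for replicate 4 (0.036 and 0.061). GABA receptors, cytokines and oligodendrocyte precursor markers no longer passed with PV replicates 1 to 3 only (adjusted p = 0.086, 0.11 and 0.089), whereas effectors and dense-core granule proteins passed on the lower side (0.031 and 0.033). Oligodendrocyte precursor markers did not pass with upper-quartile factors either (0.052).

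**Figure D5:**
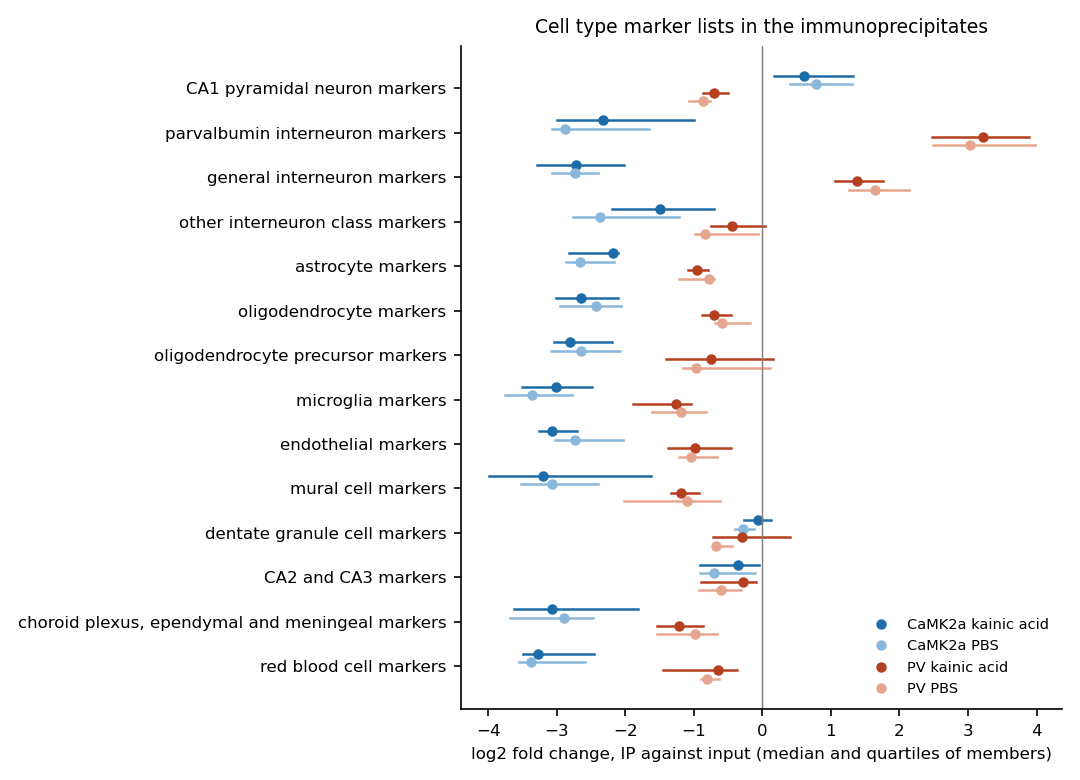
Median (point) and quartiles (bar) of the log2 fold change, IP over input, of the tested members of 14 lists of cell type markers in both lines after PBS and after kainic acid. PV interneuron markers have a median of 3.03 in the PV IP after PBS and -2.88 in the CaMK2a IP.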

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

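Tests of reactive astrocyte genes, the share of IP transcripts lower in the CaMK2a line and all tests on other splits of the libraries were chosen after the result was seen; the other tests were set before.

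Reactive astrocyte genes rose after kainic acid in both IPs, 12 of 14 in the CaMK2a IP and 12 of 17 in the PV IP, although neurons were tagged. After kainic acid their median IP to input value in the CaMK2a line lay below that of CA1 markers (difference -2.62, SD of the markers 0.740). All 18 genes were lower in the IP there, while the median of all genes tested was -0.02. These values argue against transcription in tagged cells alone in the CaMK2a line. In the PV line the median lay below that of PV markers (-4.31, SD 0.982). The median of all genes there was 0.02, against 3.21 for PV markers. A list picked without regard to kainic acid would also lie below PV markers, so this test cannot decide for the PV line. RNA of glia carried through the IP stays possible, as the medians lay within 1 SD of those of astrocyte markers, with differences of 0.174 (SD 0.575) and -0.152 (SD 0.294). Both tests took 18 genes in each line, against 14 tested for the rise in the CaMK2a IP and 17 in the PV IP. Genes can enter them through levels in the input alone, which lowers the median towards the astrocyte markers and away from the markers of tagged cells. The closeness to astrocyte markers therefore cannot decide for the genes that rose in the IP. What stays open is a part from tagged cells, as 7 of 18 genes in the CaMK2a line and 6 of 18 in the PV line lay above the highest astrocyte marker. For the PV line tagged cells as the whole source are not decided either.

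The 409 transcripts that rose in both IPs, Fos, Npas4 and Inhba among them, form the next pattern. Their median PV IP to input value after kainic acid, -0.11, lay 0.592 above that of CA1 markers (-0.70, SD 0.305). The median of all genes tested there was 0.02, so a list picked without regard to kainic acid would also lie above CA1 markers. This test therefore cannot decide whether pyramidal RNA carried through the PV IP is the whole source. The 409 transcripts were chosen partly on the same PV IP libraries, which raises their median, and 765 transcripts chosen on the CaMK2a IP and PV input instead had a median of -0.22 (SD 0.643). PV replicate 4 as the source is argued against, since without it 481 transcripts rose in both, with 110.4 expected and 379 of the 409 among them. A response shared by both cell classes remains as a hypothesis, as does carried RNA as a part or as the whole source.

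After PBS 166 transcripts other than interneuron markers were at least 4-fold higher in the PV IP than in its input, such as Sptan1 at 5.06 and Ppp1r9a at 4.91, against 0.44 and 1.00 in the CaMK2a line. RNA bound whatever the Cre line, as the whole cause, predicts few of these genes lower in the CaMK2a IP. Of the 154 tested in both lines 37.7% were lower, Kcng4 (-2.57) and Ift27 (-0.62) among them. Of all 10950 tested 3457 were lower, so a list picked without regard to the PV IP would also hold more than a few. The values argue against that cause for the genes that were lower and cannot decide for the whole set. Such binding as a part cannot be told apart from none, as 33.8% were higher in the CaMK2a IP against 33.1% of all 10950 tested (exact p = 0.86). Transcript length may contribute, since the median length of 4343 bases lay at percentile 99.3 of 10000 random lists matched on expression (median 3747.5), though 60 of the genes were not longer than that. Higher levels in PV cells stay open as a biological difference.

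Among groups of 4 libraries 18 of 148 tests found a library far from the others; chance gives about 1 in 20 groups, or 7.4 here, and 17 of the 18 were PV replicate 4. CPM in this paragraph use factors over all 16 PV libraries, so they differ from the levels in the report. In kainic acid input replicate 4 the mitochondrial share was 4.83%, the share of the 10 most abundant genes 7.94%, the mean log2 CPM of astrocyte markers 8.05, and CPM was 767 for Npas4, 1014 for Slc17a7, 10.0 for Pvalb and 3305 for Mbp. In kainic acid IP replicate 4, 29.1% of the library total was counted, and CPM was 950.5 for Fos, 725 for Inhba, 169 for Pvalb and 1508 for Gad1. PBS IP replicate 4 had a mitochondrial share of 0.795%, Camk2a at 3458 and Slc17a7 at 482 CPM, and PBS input replicate 4 had Slc17a7 at 1194 and Mbp at 2859 CPM. The remaining one was Rgs2 in PV kainic acid input replicate 1, at 434 CPM against 419 to 421 in the others.

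Effects that differ between groups by a test of the difference number 12 for CaMK2a IP minus input, 3 for PV IP minus input and 11 for CaMK2a IP minus PV IP. For CaMK2a IP minus input they include Npy at 2.52, Ptgs1 at 2.32, Unc5b at 1.95, Ednrb at 1.76, Rgs10 at 1.48, Sh3bp4 at -1.33, Klf3 at -1.55, Thbd at -1.62, Itpkb at -1.91 and Cebpd at -2.00. List medians were -0.35 for inducible transcription factors, -0.49 for MAP kinase inhibitors, 0.31 for heat shock chaperones and 0.51 for other interneuron class markers (adjusted p = 0.86, 0.86, 0.86 and 0.094 with an estimated correlation, which ended these list calls). For PV IP minus input they are Vmp1 at 1.45, Fam43a at -1.70 and Tll1 at -2.47, with a median of 0.62 for inducible transcription factors (adjusted p = 0.71 with an estimated correlation). For CaMK2a IP minus PV IP they include Tll1 at 4.51, Bag3 at 3.31, Lbh at 2.25, Cgref1 at 2.17, Ubash3b at 2.10, March4 at -1.43, Klf3 at -1.76 and Egr1 at -2.33. List medians there were -0.80 for inducible transcription factors, -0.13 for MAP kinase inhibitors, -0.22 for GABA receptors, -0.14 for sodium and calcium channels, 0.49 for cholesterol synthesis, 0.54 for heat shock chaperones, 0.38 for ribosomal proteins, -1.66 for cytokines and 0.25 for reactive astrocyte genes. With an estimated correlation none of these list calls held (adjusted p = 0.23, 0.23, 0.23, 0.23, 0.23, 0.25, 0.81, 0.23 and 0.52). The libraries on which single calls hang are named in the report.

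Other splits of the same libraries were counted for each comparison. With 3 against 3 libraries the 10 splits are too few for a share under 0.05; the real splits gave 3744 (CaMK2a IP), 3953 (CaMK2a input), 5549 and 7189 (CaMK2a IP against input after kainic acid and PBS) and 12 transcripts (CaMK2a IP minus input), and the highest other split of each gave 0 with edgeR. With 4 against 4 libraries 1 of the 35 splits, the real one, gave as many in each case, with 0 as the highest other. At both sizes every other split mixes treatments or fractions within its groups, which widens the spread and hardly lets any gene pass. The 0 of the other splits therefore does not bear on chance. For the 539 in the PV IP the replicate numbers did not pair all libraries, but those of replicate 4 resembled each other (r = 0.54), and the real split is 1 of the 20 that part them, a share of 0.05 that cannot be smaller. Numbers pair the libraries by lysate pool for the 1227 and 2077 of PV IP against input after kainic acid and PBS. For the 1289 in the PV input, and for the inputs behind the 3 of PV IP minus input, only replicate 4 clearly pairs (r = 0.80). PBS input replicates 1 and 3 resembled kainic acid input replicate 2 more than that of their own number. For the 1289 the real split is 1 of the 20 that part replicate 4, a share of 0.05. With all numbers taken as pairs in these comparisons, the real split is to be compared with the 8 splits that part all pairs, which are too few for a share under 0.05. The highest other of these gave 0, and the remaining 27 put libraries of a pair into the same group. For PV IP minus input 504 transcripts had an unadjusted p under 0.05, where chance gives 593. For CaMK2a IP minus PV IP 6 of 100 splits drawn, the real one included, gave at least 11, and the highest other gave 979. All 5 others keep the CaMK2a treatments together, as 7 of the 99 others do, so this structure of the samples is what they measure. None of the 90 splits that keep neither line together reached 11. These mix treatments within groups of both lines, which widens the spread and hardly lets any gene pass, so they do not bear on chance.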

How the results depend on the processing

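PV replicates 1 to 3 only and the term for PV replicate 4 were chosen after seeing the data; the other alternatives were set beforehand. Relative log expression and upper-quartile factors kept each count of changed genes within 1.5 times its reported value, and no gene past the threshold was called in the opposite direction under any alternative run. Outside the differences of effects the balance of counts did turn with upper-quartile factors, from more higher to more lower calls: 1674 and 2276 in the CaMK2a IP, 1896 and 2240 in the CaMK2a input, 2994 and 4196 for CaMK2a IP against input after PBS and 1019 and 1104 for PV IP against input after PBS. For CaMK2a IP against input after PBS it also turned with relative log expression factors (3576 and 3634), the stricter filter (3570 and 3591) and without CaMK2a PBS input replicate 3 (3432 and 3434). For CaMK2a IP minus input it turned with no filter (9 and 8) and without CaMK2a PBS IP replicate 2 (10 and 4) or kainic acid IP replicate 2 (29 and 14). Values below are higher and lower counts that left that range; the cause was not tested, except that fewer libraries or genes were tested where said.

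With DESeq2 the counts were 209 lower in the PV IP after kainic acid, 658 lower in the PV input, 719 lower for PV IP against input after kainic acid, 37 and 46 for CaMK2a IP minus input, 3 and 4 for PV IP minus input, and 23 and 20 for CaMK2a IP minus PV IP. With no filter on low counts CaMK2a IP minus input gave 9 higher. With a fit to all groups of a line the PV IP gave 776 and 285 and the PV input 603 and 214.

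With the replicate block the PV IP gave 248 lower, the PV input 1835 and 1590, and CaMK2a IP minus PV IP 14 higher. PV IP against input then gave 1313 and 1082 after kainic acid and 1599 lower after PBS, CaMK2a IP minus input 26 and 31, and PV IP minus input 4 and 5. Where the numbers did not pair the libraries, the block also let oxidative phosphorylation (on the falling side, adjusted p = 0.036) and other interneuron class markers (0.043) pass in the CaMK2a IP and circadian clock genes (0.032) in the PV IP. With PV replicates 1 to 3 only, which tests fewer libraries, the PV IP gave 178 lower, the PV input 1608 and 1150, PV IP minus input 4 and 6, and CaMK2a IP minus PV IP 39 and 31. With the term for replicate 4 the PV IP gave 681 and 250, the PV input 1866 and 1596, PV IP against input 1343 and 1009 after kainic acid and 1855 and 1518 after PBS, PV IP minus input 2 and 5, and CaMK2a IP minus PV IP 17 and 11.

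Lists past the camera threshold over all comparisons fell to 14 with an estimated correlation. That setting left 223 list results on the same side and ended 150. Upper-quartile factors left 358 on the same side, and the replicate block left 331.

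Leaving out 1 library at a time, which tests fewer libraries, gave 1479 to 2318 higher and 979 to 1924 lower for the CaMK2a IP, 1708 to 2357 and 1200 to 1957 for the CaMK2a input, 329 to 586 and 30 to 164 for the PV IP, and 682 to 1151 and 196 to 616 for the PV input. For IP against input the ranges were 2207 to 2749 and 2346 to 2954 (CaMK2a, kainic acid), 3386 to 3659 and 3218 to 3538 (CaMK2a, PBS), 486 to 843 and 234 to 520 (PV, kainic acid) and 839 to 1259 and 581 to 1025 (PV, PBS). For differences of effects they were 2 to 29 and 3 to 39 (CaMK2a IP minus input), 1 and 1 to 2 (PV IP minus input) and 2 to 18 and 0 to 6 (CaMK2a IP minus PV IP). The libraries behind the wide ranges are named in the report beside each count. Of the values of named genes 9502 stayed on the same side and 577 lost their call. Depth of 6.06 to 15.8 M counts and 3 or 4 libraries per group limit small changes: 2-fold changes put into simulated data were recovered at 4.48% between the IPs and 8.96% for PV IP minus input.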

Other observations

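All observations of this part were chosen after the values were seen, and they rest on the tests given in the report.

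Some ion channel and receptor lists were higher in the CaMK2a IP than in the input after PBS: GABA receptors in 12 of 14 genes, sodium and calcium channels in 13 of 19 with 4 lower, and potassium and HCN channels in 16 of 32 with 6 lower, with camera adjusted p = 1.8e-05, 0.011 and 0.015, and adjusted p = 0.14, 0.18 and 0.18 with an estimated correlation. None of these calls held with the estimated correlation, and glutamate receptors, with 7 higher and 6 lower of 15, did not pass (camera adjusted p = 0.35). Cytosolic ribosomal protein genes were lower in 43 of 66, oxidative phosphorylation genes in 36 of 56 and cholesterol synthesis genes in 17 of 20 (camera adjusted p = 7.8e-06, 0.0028 and 3.4e-05, and adjusted p = 0.21, 0.48 and 0.14 with an estimated correlation). Perineuronal net genes were lower in 8 of 12, the aggrecan gene Acan at -3.96 ± 0.52 among them (camera adjusted p = 0.0028, and adjusted p = 0.18 with an estimated correlation).

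Across genes, which are not independent replicates, kainic acid effects had a Pearson r of 0.876 between CaMK2a IP and input, 0.748 between PV IP and input and 0.880 between the inputs of both lines. IP against input values had a Pearson r of 0.921 between treatments in the CaMK2a line, 0.715 in the PV line and 0.270 between the lines after PBS.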
